A study of Mus musculus with 6 samples.

How the data were processed

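Total RNA pooled from papillomas of 2 Atf2 wild-type mice and of 3 Atf2 knockout mice was labelled with Cy3 and hybridised to Illumina mouse bead arrays, 3 per pool, all 6 on 1 chip. The wild-type pool took the first 3 positions of the chip and the knockout pool the last 3. The 6 arrays were grouped by the genotype in their titles, and every array was used.

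The deposited file of each array holds raw intensity per probe on a linear scale, per the file headers, with no detection p and no control probes. The lowest values lie far above 0, so no background seems to have been subtracted. BeadStudio 3 is named in the submitters' processing notes. The authors also deposited a table of log2 values for the same arrays, in which all 6 columns share a common distribution and each column keeps the rank order of that array's raw intensities, as quantile normalization leaves them. At its low end this distribution lies above the mean of the sorted raw values, and the exact method is not given in the sources used here. That table was used as an alternative.

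The design fixed before the data were examined foresaw raw signals with a detection p, signals already normalized or background-subtracted signals. The files held raw signals without detection p, so the raw intensities were background-corrected with limma's normexp method and an offset of 50, converted to log2 and quantile-normalized. The offset shrinks differences of dim probes. Probes whose mean log2 intensity over the 6 arrays was above the median of all 46116 probes were tested, which left 23058. Each probe was tested between the pools with limma (lmFit, then eBayes with an intensity trend; R 4.3.3, limma 3.58.1), with Benjamini-Hochberg adjustment over the tested probes and with two-sided p-values. A probe passed the threshold with an adjusted p under 0.05 and an absolute log2 difference of at least 1. Because the arrays of a pool are technical replicates, these p-values measure technical spread and the size limit carries the call.

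Each array's background was taken as the mode of its raw intensities, and a probe was called above background when it exceeded the mode by 3 SDs, the SD being computed from the values below the mode. This rule was added after the data had been seen. A probe not above background on any array of a pool was given only a bound there: the brighter pool's mean against the dimmer pool's mean of, per array, the higher of the lowest normalized value among probes above background and the probe's own value. Where a probe given with its value passed the threshold in the main setting and a pool was partly above background, the number of arrays is given. For other probes it is not always given.

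Genes were named from GEO's platform annotation of the array, which can hold old symbols. Of the 46116 probes, 29534 had 1 symbol, 11 had several and 16571 had none or were not listed. Symbols of 29476 probes were looked up through their Entrez identifiers in a RefSeq gene table of assembly GRCm38.p6, and 0 changed. A gene was represented by its tested probe with the highest mean signal. Gene positions from the same table were used only to compare chromosomes and to find the neighbours of Atf2. Probe sequences and their positions in the transcripts were not used here.

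Fixed before the data were examined were the threshold, the 34 gene lists, the rule for naming genes and most of the alternatives tried. Named genes are 10 chosen in advance (1 of them is not reported here), the 8 largest rises and 8 largest falls among genes past the threshold whose arrays did not overlap between pools and that were above background on all arrays of the brighter pool, and, for each list described at length, up to 2 rises and 2 falls past the threshold or, with none, its brightest member. The largest rises and falls were taken on the probe that represents the gene. Genes with placeholder symbols, such as RIKEN clones, were left out of them. A list is described at length if its median lay outside the central 95% of its random lists or if at least 5 members passed. Each list's median log2 difference was set beside the medians of 10000 random lists of the same size drawn from 20 bins of mean signal. This describes these 2 pools and gives no p-value. Intervals of medians are bootstrap intervals from 10000 draws over genes, and those of shares are exact binomial intervals.

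The test was checked on simulated arrays with the same number of probes in the fit (23058). In these, 50 probes were changed at each of 4 sizes. They were drawn from all tested probes, dim ones included, and only their signal over background was changed. The noise was taken from raw values before normalization, and changed probes that were not tested counted as misses. Recovery among probes well above background was not measured apart. A change of 2-fold passed the threshold in 6% of its probes, 3-fold in 36% and 4-fold in 64%, with median sizes found of 0.5, 0.926 and 1.16 on the log2 scale, and 0 of 22871 unchanged probes passed.

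Alternatives covered the offset, the background correction, scaling in place of quantile normalization, the filter, the authors' table, a replicate block, array weights, the fold limit, the test, every other probe of a named gene, any tested probe of a gene in place of the brightest and leaving out each array in turn. The neqc method with detection p was planned and could not be run, because the files used here hold neither detection p nor control probes.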

Results

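Transcript levels were measured in skin papillomas of Atf2 wild-type and Atf2 knockout mice on 6 Illumina bead arrays. Atf2 encodes a transcription factor of the ATF and CREB family. The mice came from a mix of the FVB and C57bl6 strains and carried papillomas, benign skin tumours, at about 9 months of age. The tumours were induced with 1 application of the mutagen DMBA followed by 30 weeks of the tumour promoter TPA. Total RNA from the papillomas of 2 wild-type mice made up 1 pool, RNA from those of 3 knockout mice made up the other, and each pool was hybridised to 3 arrays of the same chip. The 3 arrays of a pool were technical replicates, so each SD, SE and p-value given here measures technical spread, and the comparison is between 2 RNA pools with no replicate check of the genotype. The position on the chip also coincided with genotype.

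The arrays carried 46116 probes. Median raw intensity was 140.8, 135.8 and 148.2 on wild-type arrays 1, 2 and 3, and 135.5, 124.5 and 109.9 on knockout arrays 1, 2 and 3. Between 31.7% and 33.3% of the probes were above background on the wild-type arrays and between 28.1% and 29.9% on the knockout arrays. Across probes, the correlation of normalized log2 intensity was 0.9878 to 0.9966 between arrays of the same pool and 0.947 to 0.9536 between arrays of different pools; probes are not independent replicates. The median SD between the arrays of a pool was 0.11 on the log2 scale. The number of arrays, 3 per pool, limits the precision of every value.

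The targeted gene was near background in both pools. Of 4 Atf2 probes, 3 were at background on all 6 arrays. The remaining probe (2260348) read 184.5, 176.2 and 186.3 on the wild-type arrays and 171, 133.2 and 103 on the knockout arrays, with a mean of 182 ± 5.39 (SD, n = 3) against 136 ± 34.1 (SD, n = 3). It was above background on all 3 wild-type arrays and on 1 knockout array, and its log2 difference of -0.28 (SE 0.13) did not pass limma's test (adjusted p = 0.109). Where these probes lie relative to the deleted part of the gene is not given in the sources used here, so they do not check the genotype labels. Signed values are the knockout pool minus the wild-type pool throughout.

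Other genes fixed in advance lay within 2-fold of the wild-type pool. Atf7, a close relative of Atf2, was 0.69 higher on the log2 scale (SE 0.08, limma adjusted p = 3.64e-05), and the receptor gene Notch1 was 0.53 higher (SE 0.12, adjusted p = 0.00289). The brightest probe of Ctnnb1, which encodes beta-catenin, was at -0.77 (limma adjusted p = 0.000417). Its other probe, a dim one (raw intensity 281.3 in the wild-type and 295.9 in the knockout pool), was at 0.48 (adjusted p = 0.0015). For Ccnd1, which encodes cyclin D1, the 4 probes were at 0.35, 0.52, 0.20 and 0.49. Cdkn1a, the p21 gene, was at 0.40 on its brightest probe and at -0.13 on the other, and Jun was at 0.35. Krt14, a keratin of the basal epidermis, was at -0.07 (adjusted p = 0.477), close to the top of the intensity range. None of these differences reached the 2-fold limit. Trp53 was not analysed here.

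The 8 largest rises in the knockout pool, on brightest probes and with placeholder symbols left out, were each in a gene with a single tested probe. In each the 3 knockout arrays lay above the 3 wild-type arrays. Krt15, a keratin of basal keratinocytes and the hair follicle bulge, rose 8.67-fold, from a raw intensity of 402 ± 8.35 to 2629 ± 201 (SD, n = 3 arrays each; log2 difference 3.12, SE 0.09, limma adjusted p = 4.15e-10). Serpina12, which encodes the protease inhibitor vaspin, was not above background on the wild-type arrays and was at least 7.57-fold higher in the knockout pool (adjusted p = 5.14e-10). Sgip1, an endocytic adaptor gene, rose by 2.46 on the log2 scale and Retnlg, a resistin-like gene of neutrophils, by 2.41. Mt4, the metallothionein of stratified epithelia, and Gsta3, a glutathione transferase gene, were not above background in the wild-type pool and were at least 3.45-fold and at least 3.40-fold higher. Wfdc21 rose by 1.94 and Defb3, a beta-defensin gene, by 1.80.

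Taken by the same rule, the 8 genes with the largest falls each had other tested probes, some of them close to background. The brightest probe of Hnrnpa2b1, which encodes an RNA-binding protein, fell by 3.15 on the log2 scale (raw intensity 4261 ± 294 to 440 ± 75.1, SD, n = 3 arrays each; limma adjusted p = 6.76e-08), while other probes were at -0.92 (raw intensity 1620 in the wild-type pool) and -0.39 (307.3) and a further probe was not above background on any array. Suclg1, a gene of the citric acid cycle, fell by 3.02 on its brightest probe with the other, a dim probe (233.7), at -0.42. For the tetraspanin gene Tspan3 these values were -2.90 and -0.06, the latter from 302.9. Atf4, which encodes the transcription factor of the integrated stress response, fell by 2.65 (adjusted p = 1.38e-09), and its other probe was not above background on any array. The brightest Gnas probe, for the alpha subunit of the stimulatory G protein, was not above background on the knockout arrays and was at least 4.77-fold lower, while of the other Gnas probes, also dim (307.9, 191.8 and 176.2), 1 was likewise only bounded, at least 1.77-fold lower, and the others were at 0.25 and 0.06. Hnrnpk, another gene of the hnRNP family, fell by 2.87 on its brightest probe; a pair of probes not above background on the knockout arrays was at least 4.75-fold and at least 1.33-fold lower, and a dim probe (194.2) was at -0.05. In Btg1, an antiproliferative gene, both probes fell, the brightest by 2.92 on the log2 scale and the other, not above background on the knockout arrays, at least 9.31-fold. In Tnfrsf22, which encodes a decoy receptor for TRAIL, a pair of probes was at -3.10 and -3.09, and a further probe was above background on 1 wild-type array only. Suclg1 and Hnrnpk were above background on 2 of the 3 knockout arrays on the probes that represent them.

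**Figure D1:**
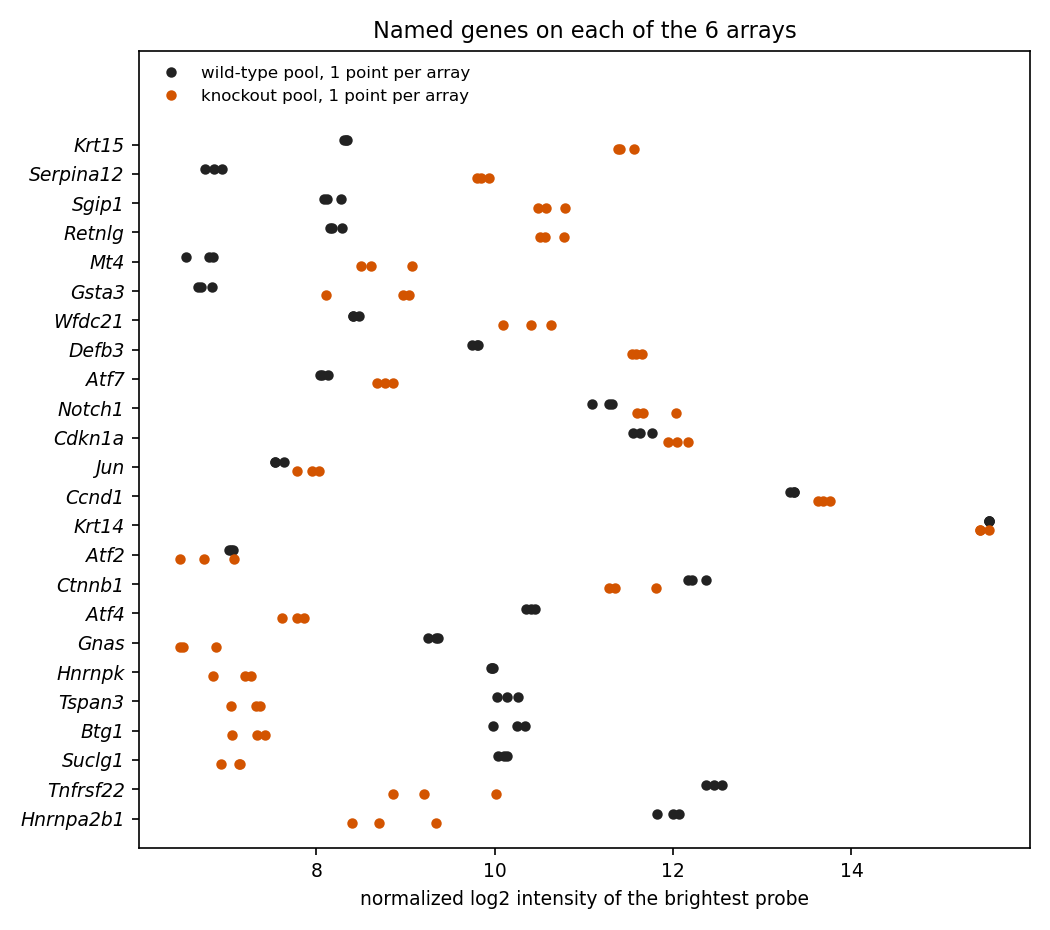
Normalized log2 intensity (x axis) of the genes named in advance and of the 8 genes with the largest rises and the 8 with the largest falls, each on its brightest tested probe. Each point is 1 array, black for the wild-type pool and orange for the knockout pool; the arrays of the 2 pools overlap for Atf2 and Krt14 and are apart for the other genes drawn.

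In all, 1126 of 23058 tested probes passed the threshold of an adjusted p under 0.05 (limma, Benjamini-Hochberg) and a difference of at least 2-fold, of which 227 were higher and 899 lower in the knockout pool. With 1 probe per gene, 435 of 12096 genes passed, 135 higher and 300 lower. Counting a gene when any of its tested probes passed gave 158 higher and 651 lower, 4 of them in both. At 4-fold or more, 5 genes were higher and 38 lower. The probe that represents the gene was not above background on any knockout array for 62 of the 300 lower genes, and on any wild-type array for 16 of the 135 higher genes. The adjusted p alone was passed by 8882 probes, 54.2% of them higher. The count of probes past the threshold was 748 with the authors' normalized values, 633 among probes above background on all 6 arrays and 2026 with each array's background mode subtracted and a floor of 50, a setting added once the data had been seen.

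**Figure D2:**
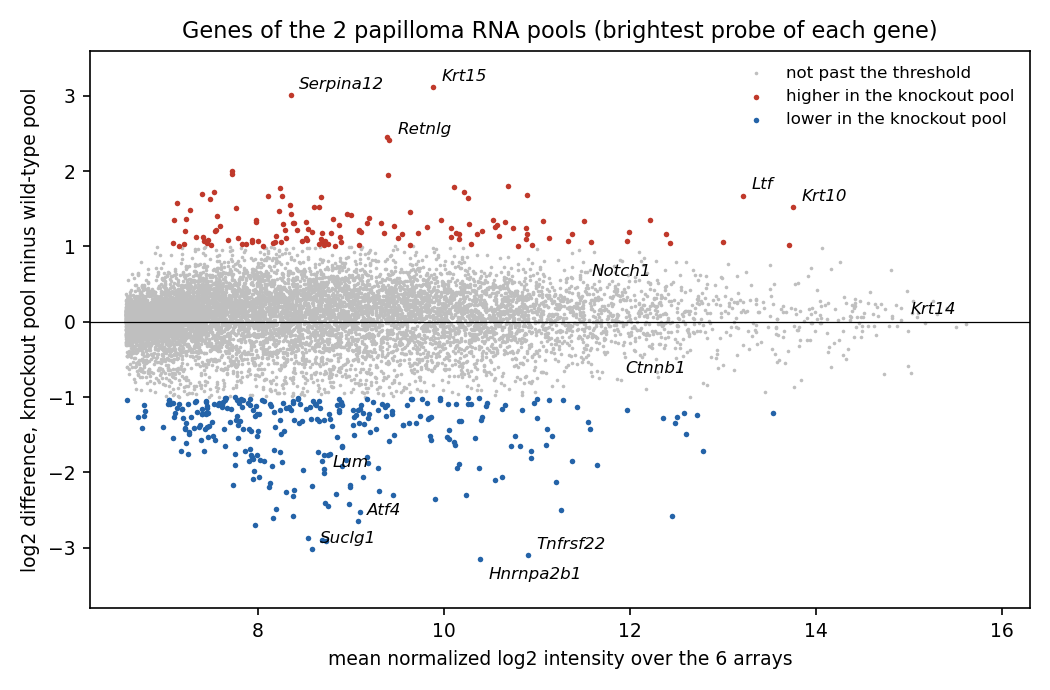
Log2 difference between the pools (y axis) against mean normalized log2 intensity over the 6 arrays (x axis) for 12096 genes, each on its brightest tested probe. The 135 genes higher in the knockout pool are red, the 300 lower are blue, and the falls reach past -3 at low and middle intensities.

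Falls were often seen on some probes of a gene and not on others. Of 2078 genes in which at least 2 tested probes were above background on all wild-type arrays, 445 had at least 1 such probe that fell past the threshold; in 28 of these genes all such probes fell, and in 290 (65.2%, exact 95% interval 60.5 to 69.6) another probe was above -0.25. For Krt6a, a keratin of activated epidermis, probes at raw intensities of 15930 and 12330 in the wild-type pool both fell by 3.90 (log2). Its brightest probe, at 42220 and so towards the top of the intensity range, was at -0.58. The tubulin gene Tubb5 had probes at -3.54 (above background on 1 knockout array) and 0.15, and the sulfotransferase gene Sult2b1 at -3.29 and 0.04. In the acid sphingomyelinase gene Smpd1 both probes fell, the brightest by 2.19 and the other, not above background on the knockout arrays, at least 6.77-fold. These examples were chosen after their values were seen. Among 1475 genes with at least 2 probes above background on all knockout arrays, 48 had a probe that rose, and in 24 of them (50%, interval 35.2 to 64.8) another probe was below 0.25. A gene said to fall is therefore one whose brightest probe fell, and counts over any tested probe, added after the data had been seen, are given where they differ.

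**Figure D3:**
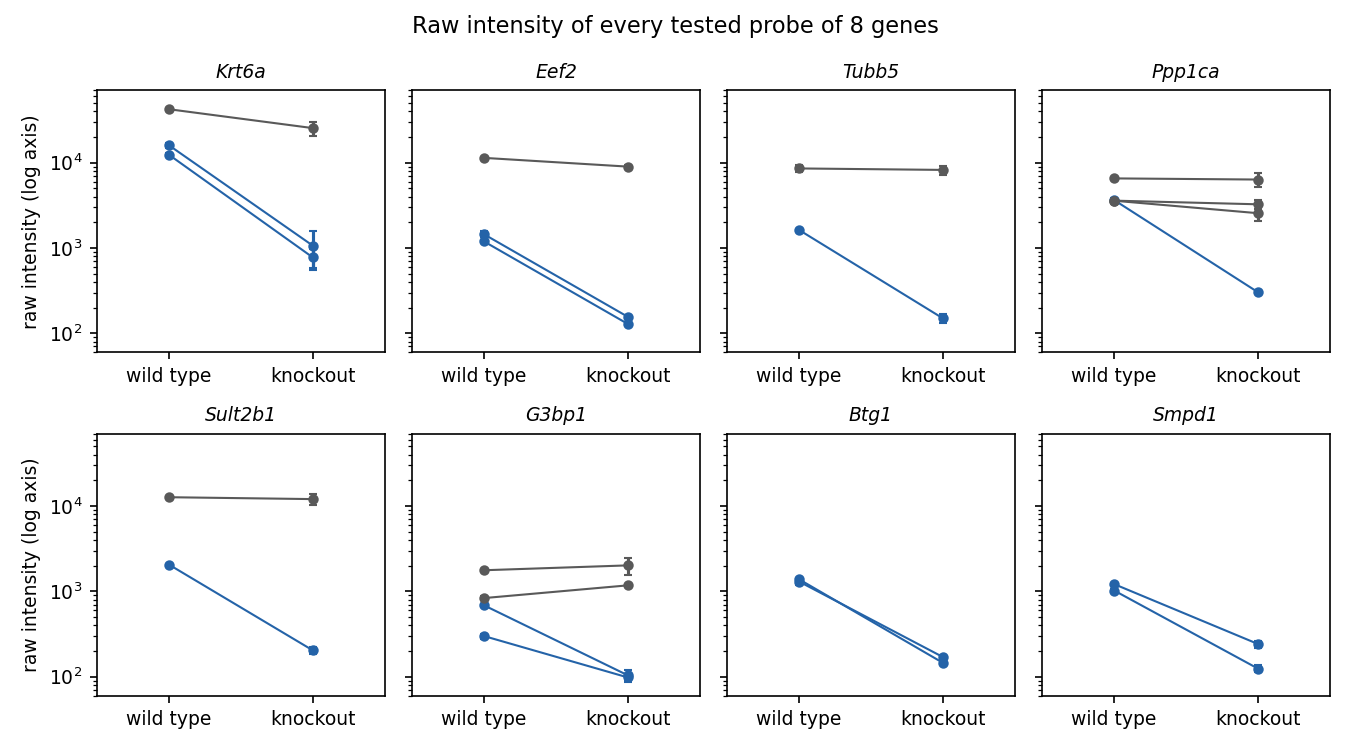
Raw intensity (log y axis) of every tested probe of 8 genes in the wild-type and the knockout pool, 1 line per probe; points are means and bars SDs of 3 arrays. Blue probes fell past the threshold and grey ones did not: in Krt6a, Eef2, Tubb5, Ppp1ca, Sult2b1 and G3bp1 both kinds occur, while in Btg1 and Smpd1 both probes fell.

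Among genes of the granular layer and cornified envelope, the outermost living and dead layers of the epidermis, the late cornified envelope 1 family was higher in the knockout pool. Of 35 tested genes 8 rose and 2 fell, and the list's median log2 difference of 0.25 lay at percentile 99.7 among 10000 random lists matched on signal. Split after the values were seen, the 11 late cornified envelope 1 genes had 7 of the rises and a median of 1.07, and the other 24 genes had 1 rise, Casp14 (1.06; 0.94 without knockout array 3), the 2 falls and a median of 0.0163 that lay inside the random range (percentile 17.2). The rises were led by Lce1a2 (1.34, SE 0.08, limma adjusted p = 1.17e-07) and Lce1i (1.33, SE 0.12, adjusted p = 2.55e-06). The falls were Scel (-1.28), which encodes sciellin, and Ivl (-1.01), which encodes involucrin; both proteins belong to the cornified envelope. Ivl lay just past the 2-fold limit and was within it under 7 other settings and without wild-type array 3 (-0.995), knockout array 1 (-0.952) or knockout array 3 (-0.996).

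Among 12 spinous keratinocyte genes, which mark the layer above the basal cells, 2 rose and 3 fell, with a median of 0.03 that lay inside the random range and was below 0 under 3 other settings. Krt10, a keratin of spinous cells, rose 2.88-fold, from 8816 ± 303 to 22310 ± 1156 (SD, n = 3 arrays each; limma adjusted p = 6.32e-08), beside Mt4. The epidermal transcription factor gene Grhl3 fell by 2.48 on the log2 scale (above background on 1 knockout array), Sfn, the 14-3-3 sigma gene, by 1.85, and Elf5, named because it completes the count, by 1.15 (-0.98 with the authors' values). Each of these genes had a single tested probe. Among 23 hair follicle genes 3 rose and 2 fell, with a median of -0.20 (percentile 0; -0.207 to -0.128 when each array in turn was left out). The homeobox gene Dlx3 rose by 1.17, the hair keratin gene Krt84 by 1.20 and S100a3 by 1.04, the last named to complete the count; Krt84 was above background on 1 wild-type array, and with the authors' values and with an offset of 100 both Krt84 (0.92 and 0.95) and S100a3 (0.92 and 0.93) stayed under 2-fold, which left 1 rise. The keratin genes Krt27, of the inner root sheath and not above background on the knockout arrays, and Krt79 fell, by at least 1.94-fold and by 1.21 on the log2 scale.

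Genes of fibroblasts and their extracellular matrix were lower in the knockout pool. The median over 39 tested genes was -0.445 (percentile 0 among matched random lists), 29 of the 39 had negative values, and 4 fell past the threshold with no rise. Lum, which encodes the collagen-binding proteoglycan lumican, fell 4.03-fold (raw intensity 955 ± 79.0 to 216 ± 24.7, SD, n = 3 arrays each; limma adjusted p = 5.82e-09). Both probes of the fibronectin gene Fn1 fell, the brighter one by 1.32 on the log2 scale (above background on 2 knockout arrays) and the other, not above background there, at least 1.94-fold. The others, named because they complete the count, were the fibrillar collagen genes Col1a1 (-1.12) and Col3a1 (-1.11). On another probe Dcn, the decorin gene, also fell (-1.83, above background on 1 knockout array; brightest at -0.72). The medians of 21 endothelial genes (0.0248) and 12 smooth muscle and pericyte genes (-0.0159) lay inside their random ranges. None of these genes passed the threshold on its brightest probe, but another probe of Acta2, smooth muscle actin (brightest at -0.52), passed it and was at least 1.63-fold lower, as did another of the pericyte gene Rgs5 (brightest at 0.67), at least 1.67-fold lower, neither being above background on the knockout arrays; Dcn and Rgs5 were chosen after their values were seen. At an unadjusted limma p under 0.05, with no fold limit, 4 endothelial and 3 smooth muscle and pericyte genes were higher on their brightest probes and 6 and 3 lower.

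Skeletal muscle genes were also lower, with a median of -0.24 over 30 tested genes (percentile 0), 2 falls and no rise. Over the settings with all arrays the median ran from -0.314 to -0.137. There were 3 falls without knockout array 1 and 4 without knockout array 2. The falls were Acta1, skeletal alpha-actin (-1.09, SE 0.12, limma adjusted p = 1.65e-05), and Myl1, a myosin light chain gene that was not above background on the knockout arrays (at least 1.43-fold lower). Acta1 was at -0.95 without knockout array 3, and Myl1 at -0.77 with the authors' values, both within the 2-fold limit. Erythrocyte genes were higher, with a median of 0.64 over 9 tested genes (percentile 100), 2 rises and no fall. Alas2, which encodes the erythroid enzyme of haem synthesis, rose by 1.46 (adjusted p = 9.08e-08) and the alpha-globin gene Hba-a1 by 1.01 (adjusted p = 2.81e-06), the latter from 10130 ± 250 to 17730 ± 1260. Hba-a1 was just under 2-fold without wild-type array 1 (0.998), wild-type array 2 (0.992) or knockout array 3 (0.941). Genes of melanocytes and Schwann cells had a median of -0.18 over 12 tested genes (percentile 0.53) and none passed the threshold on its brightest probe; Mal, the brightest member, was at -0.68, and of its other probes 1 was at -1.67 and 1 was not above background on the knockout arrays (at least 1.06-fold lower).

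Macrophage and monocyte genes moved both ways, with 3 rises and 2 falls among 27 tested genes and a median of 0.02, inside the random range and below 0 after scaling to the 75th percentile. Gpnmb, a transmembrane glycoprotein gene of macrophages, rose by 1.65 on its brightest probe (limma adjusted p = 5.39e-08), with another, dim probe (243.9) at 0.42 and a further one not above background on any array. Mmp12, macrophage elastase, rose by 1.52, and Chil3, named to complete the count, was not above background in the wild-type pool and was at least 1.72-fold higher; it did not pass with the authors' values (0.75). Fcer1g, which encodes the gamma chain of Fc receptors and was not above background on the knockout arrays, was at least 2.39-fold lower, and the brightest probe of Lyz2, a lysozyme gene, fell by 1.40, the other not being above background on any array. Mast cell genes had a median of -0.12 over 10 tested genes (percentile 1.15) with none past the threshold, and the brightest member, Tpsab1, was at 0.76; the median was above 0 among probes above background on all 6 arrays, where 2 genes were left. Of 30 genes of matrix proteases and tumour progression, 1 rose and 1 fell, with a median of -0.09 (percentile 0.39). The rise was Mmp12 and the fall was in Plat, tissue plasminogen activator (-1.23, adjusted p = 3.06e-07), whose other probe was not above background on any array. On other probes Cd44 and Mmp13 of this list also fell, chosen after their values were seen.

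**Figure D4:**
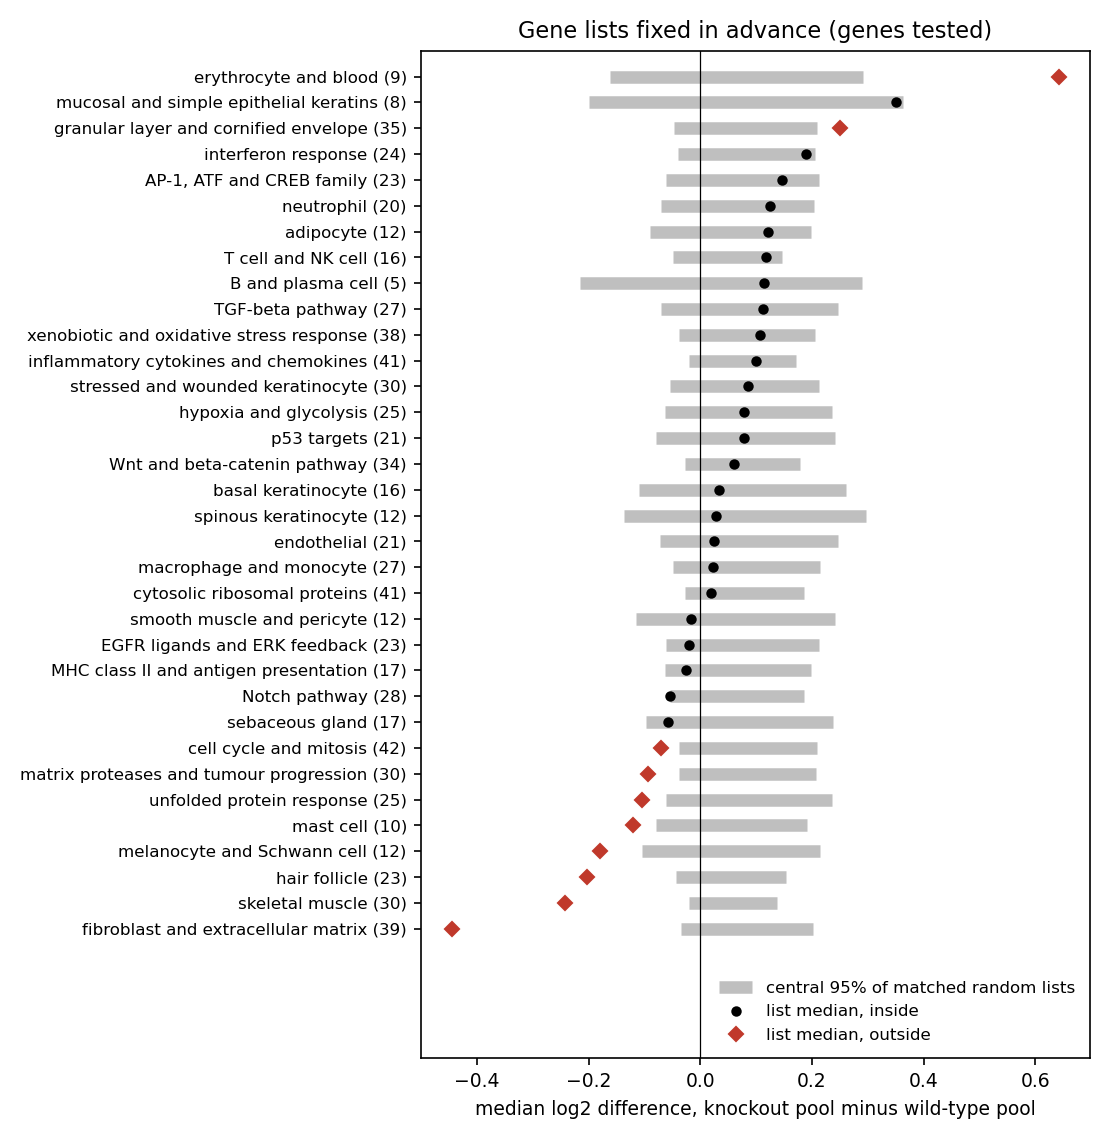
Median log2 difference between the pools (x axis) for each of 34 gene lists, with the number of genes tested in parentheses. Grey bars are the central 95% of 10000 random lists matched on signal; red diamonds lie outside them, from -0.445 for fibroblast and extracellular matrix genes to 0.643 for erythrocyte genes, and black points lie inside.

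Cell cycle genes lay slightly low, with none past the threshold on its brightest probe: the median over 42 tested genes was -0.07 (percentile 0.66; -0.125 to -0.0375 when each array in turn was left out), and the brightest, Cenpa, which encodes a centromeric histone, was at -0.18 (limma adjusted p = 0.119). At an unadjusted p under 0.05 with no fold limit, 4 of the cell cycle genes were higher and 13 lower, against 2 and 3 in the mast cell list and 2 and 5 in the melanocyte and Schwann cell list. On other probes Birc5 (-1.49), Tk1 (-1.11) and Cdc20 fell, the last on a pair of probes not above background on the knockout arrays (at least 3.74-fold and at least 3.94-fold), and Mcm6 (1.28) rose, chosen after their values were seen. Of 25 genes of the unfolded protein response 2 fell and none rose, with a median of -0.10 (percentile 0.895; -0.115 to -0.032 when each array in turn was left out). These were Atf4 and Herpud1, a gene of endoplasmic reticulum-associated degradation that fell by 1.80 (SE 0.09, adjusted p = 2.73e-08) and was above background on 2 knockout arrays. When every tested probe of a gene was averaged, the medians of this list (percentile 9.86) and of the matrix protease list (percentile 5.16) were no longer outside the random range, while those of mucosal and simple epithelial keratins (0.374, percentile 99.8) and of EGFR ligands and ERK feedback (-0.126, percentile 1.06) came to lie outside it.

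The remaining lists stayed inside their random ranges with fewer than 5 genes past the threshold, each gene being on its brightest probe. The Notch pathway median, -0.0544, lay at the low edge of its range, which began at -0.0545 (percentile 2.51). Among random lists not matched on signal it lay at percentile 1.69. Over the settings with all arrays this median ran from -0.0639 to 0.0258. In the pathway lists nearest to the targeted gene, no gene rose and 1 fell among 23 of the AP-1, ATF and CREB family, and none of 28 Notch pathway genes, 34 Wnt and beta-catenin genes or 27 TGF-beta pathway genes passed, although without knockout array 3 Myc (-1.21) of the Wnt list and Ltbp1 (1.09) and Inhbb (-1.02) of the TGF-beta list did. In the keratinocyte lists, 1 of 16 basal genes rose and none fell, 3 of 30 stress and wounding genes rose and 1 fell, and none of 8 mucosal and simple epithelial keratins passed. None of 17 sebaceous gland genes rose and 2 fell, and none of 12 adipocyte genes rose and 1 fell. In the immune lists, 4 of 41 cytokine and chemokine genes rose and none fell, 2 of 20 neutrophil genes rose and none fell, and 1 of 17 antigen presentation genes fell and none rose. Of the 4 cytokine and chemokine rises, Ccl11 (0.97) and Cxcl9 (0.93) stayed under 2-fold with the authors' normalized values. No gene passed among 24 of the interferon response, 16 of T and NK cells and 5 of B and plasma cells. Of 21 p53 targets 1 fell and none rose, and of 23 EGFR and ERK feedback genes 1 rose and 1 fell. Of 38 xenobiotic and oxidative stress genes 1 rose and 3 fell, of 25 hypoxia and glycolysis genes 1 rose and 2 fell, and none of 41 cytosolic ribosomal protein genes passed. In the lists of this kind with none past the threshold, limma gave an unadjusted p under 0.05, with no fold limit, for 6 higher and 5 lower Notch genes, 11 and 9 Wnt genes, 10 and 4 TGF-beta genes, and 5 and 1 mucosal keratins. These counts were 10 and 2 for interferon, 7 and 0 for T and NK cells, 2 and 1 for B and plasma cells, and 11 and 11 for ribosomal proteins. In each of the 34 lists, the counts adjusted over the list alone, in both directions, were equal to those over all genes tested. Counting any tested probe, further falls were seen in Cd44 of the Wnt list, Cd151, Col17a1 and Cdh3 of the basal list, Krt6a and Gjb2 of the stress and wounding list, Dusp6 of the EGFR and ERK list, Il24 and Il1a of the cytokine list and Psmb8 of the interferon list. They were also seen in H2-Ab1 of the antigen presentation list, Sdc1 of the B and plasma cell list, Gstp1 of the xenobiotic list, Hk1 and Tpi1 of the hypoxia list and the ribosomal protein genes Rps3 and Rps6. Further rises were in Itga6 of the basal list and Ski of the TGF-beta list. In the lists described at length, Asns (-1.79, above background on 1 knockout array) of the unfolded protein response and Lce3b (-1.41) of the cornified envelope fell on another probe and the beta-globin gene Hbb-bs (1.07) rose. These genes were named after their values were seen.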

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

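The settings without background correction, with the background mode subtracted and with 2 ranges of probe numbers normalized separately were added after the data had been seen; neqc could not be run without detection p or control probes. The count of 1126 probes past the threshold, 20.2% of them higher in the knockout pool, stayed within 1.5 times with offsets of 25 (1468, 22.8% higher) and 100 (775), median scaling (1119), scaling to the 75th percentile (1133, 17.9% higher), no filter (1133), separate ranges (1089), no background correction (855), array weights (1177), treat against a 1.5-fold change (1388, 25.4% higher) and a rule with no test (1127 probes 2-fold apart without overlap; chance parts 3 arrays from 3 in 10% of cases). It left that range with the authors' values (748), with probes above background on all 6 arrays (633, 28.9% higher; fewer probes were tested), with the mode subtracted and a floor of 50 (2026, 36.3% higher), with a 1.5-fold limit (3247, 39.1% higher) and with the adjusted p alone (8882, 54.2% higher); apart from the smaller number tested and the looser limits, the cause was not tested. Leaving out each array in turn gave 1093 to 1228 probes and 20 to 21.4% higher. With a replicate block the count was 1128 (20.1% higher); the labels' replicate numbers do not pair the arrays, whose deviations correlated at 0.11, -0.13 and 0.04, and for 0 of the 3 numbers did the arrays correlate best with each other. The median over all tested probes was 0.0535 in the main setting, 0.135 with median scaling, 0.101 with the 75th percentile and 0.117 among probes above background on all arrays. The mast cell median turned to 0.0493 in the last of these, where 2 of its 10 genes were tested; the medians of the other lists outside their random ranges kept their sign under every setting run, though some moved by more than 1.5 times. The hair follicle median of -0.203 ran from -0.207 to -0.128 when each array in turn was left out and from -0.266 to -0.082 over the other settings; for cell cycle genes (-0.071) these ranges were -0.125 to -0.0375 and -0.128 to -0.0262, and for the unfolded protein response (-0.104) -0.115 to -0.032 and -0.109 to -0.0187. Over the other settings the matrix protease median (-0.0933) ran from -0.137 to -0.0125; the causes were not tested. No named gene that passed the threshold passed it in the other direction under any setting. Of the list genes that passed, Ivl, Krt84, S100a3, Elf5, Chil3, Casp14, Lce1b, Lce1c, Sprr2b, Ccl11, Cxcl9, Cidea, Myl1, Acta1, Hba-a1 and Slc2a3 fell under 2-fold in 1 or more. Other list genes passed only in alternatives: apart from further ones with the mode subtracted, these were Myc, Ltbp1, Inhbb, Krt4, Il1r2, Cxcr2, Ucp1, Rpl22, Sesn1, Pmaip1, Mmp9, Il1a, Il23a, Hbb-bs, Sparc, Dst, Mgst1, Pparg, Krt34, Krtap6-1, Tcap, Myh4, Chac1 and Edem1. Signal over background limits dim probes, whose differences the offset shrinks.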

Other observations

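The groups by symbol, the comparison of chromosomes and the tests of probes differing within a transcript over all genes, of every stromal type and of falls among genes of like signal, were chosen only after the results were seen; the other tests were set beforehand. Of 5 tested genes of the HoxC cluster, which pattern the posterior body, 3 were higher in the knockout pool: Hoxc8 by 1.68 and Hoxc6 by 1.33 on the log2 scale, and Hoxc9, not above background in the wild-type pool, by at least 2.73-fold. Hoxc10 was at 0.15 and Hoxc13 at -0.02, and none of the other Hox genes among 21 tested passed the threshold. The late cornified envelope 1 family moved together, with positive values in all 11 tested genes, a median of 1.07 and 7 past the threshold, also without knockout array 3 (7 past, median 1.15) and under median scaling (7 past, median 1.13). Of 2 tested genes of the late cornified envelope 3 family, none passed on its brightest probe and another probe of Lce3b was at -1.41. The Sprr2 genes of the same epidermal differentiation complex had 2 of 9 past the threshold, both higher. With the authors' normalized values 1 of 9 passed.

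Over all genes, 300 of 12096 fell on the brightest probe and 651 on any tested probe. The groups below were taken by the start of the gene symbol, so some also hold regulators or partners of the named proteins. In groups of housekeeping genes, on brightest probes, among hnRNP, Sm and SR splicing proteins 5 of 38 fell, among Rab, Arf and coat proteins of vesicle traffic 7 of 73, among proteasome subunits 3 of 41 and among mitochondrial ribosomal proteins 3 of 74, with no rise in these groups. Their median log2 differences were -0.109 (percentile 0.17 of matched random lists), 0.0121 (percentile 3.86), 0.0717 (percentile 38.6) and 0.0492 (percentile 17.3), and 22 of the proteasome and 42 of the mitochondrial ribosome genes had positive values. With any tested probe these counts were 11, 13, 12 and 10, with 1 rise, in a splicing protein gene with probes both ways, Srsf10. Of 7 genes of 14-3-3 proteins 2 fell, Sfn (-1.85) and Ywhaq (-2.36), with a median of -0.585 (percentile 0.08). Of 9 chaperonin CCT genes 1 fell on its brightest probe, Cct3 (-2.25), and 2 fell on any tested probe. The other was Tcp1, at -2.68 on another probe and at -0.38 on its brightest. The chaperonin median was -0.178 (percentile 2.46). The group of symbols that start with Eif or Eef held 57 genes, translation initiation and elongation factors and some of their regulators. On brightest probes 1 rose, Eef2k (1.13), which encodes a kinase of an elongation factor, and 1 fell, Eif3b (-1.77). On any tested probe 10 fell. Among them were Eif5a (-3.39), Eef2 (-3.26, above background on 1 knockout array) and Eif3c (-3.33, above background on 2). Another Eef2 probe and 1 of Eif4g2, not above background on the knockout arrays, were at least 7.94-fold and at least 7.06-fold lower. The brightest probes of Eif5a and Eef2 were at -0.14 and -0.19. The median of this translation factor group was -0.0909 (percentile 0.08). The proteasome gene Psmd13 had probes at -3.41 and 0.32. Under median scaling and without knockout array 3 the medians were -0.00101 and -0.165 for splicing proteins, 0.0831 and 0.0347 for vesicle traffic, 0.135 and 0.0917 for the proteasome, 0.101 and 0.0776 for the mitochondrial ribosome, -0.62 and -0.469 for 14-3-3 proteins, -0.089 and -0.225 for the chaperonin and -0.00316 and -0.0176 for translation factors. Among 6012 tested probes without a named gene 64 were higher and 147 lower. The largest rise on the arrays was on such a probe, probe_5860167, at least 21.5-fold higher (raw intensity 102 ± 5.90 to 2555 ± 670, SD, n = 3 arrays each), and probe_104060685 was at least 5.36-fold higher; probe_5390102 and probe_6040093 were at -3.45 and -3.36 on the log2 scale.

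By chromosome, with genes placed through the RefSeq table of assembly GRCm38.p6, chromosome 6 had the lowest median log2 difference, -0.0212 over 629 tested genes with 3 higher and 27 lower, against a median of 0.0825 over genes of the other chromosomes. It stayed the lowest under each of the 19 settings in which chromosomes were compared, and its genes, split into 3 equal blocks along the chromosome, had medians of 0.0129, -0.0486 and -0.0265. Medians of chromosomes 3, 8, 11, 13 and 17 also lay outside the central 95% of random gene sets. Copy number was not analysed here, and the cause of these shifts was not tested.

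Of the 1126 probes past the threshold, 79.8% were lower in the knockout pool. This share depended on the size limit and on how dim probes were handled. It was 60.9% with a 1.5-fold limit and 45.8% with the limma adjusted p alone. It was 71.1% among probes above background on all 6 arrays and 63.7% with the background mode subtracted. Scaling between arrays, the dim knockout array 3 and a single range of probe numbers are each argued against as the sole source of the excess of falls. At least 79.4% were lower under every scaling run and 78.8% without knockout array 3. In the range with fewer falls 60.9% (95% interval 54.5 to 67) were lower. A lower yield of all abundant transcripts stays open. The cytosolic ribosomal protein median was 0.0189 (interval -0.119 to 0.107) after quantile normalization, which gives all arrays the same distribution. These genes lie near its top (mean log2 intensity 13.47 in the wild-type pool). A fall shared by abundant transcripts would be largely removed there. Before normalization the 95th percentile of raw intensity was 1410, 1438 and 1374 on wild-type arrays 1, 2 and 3. It was 1358, 1271 and 1022 on knockout arrays 1, 2 and 3. Of the multi-probe genes with a fall 65.2% (interval 60.5 to 69.6) had another probe above -0.25. That part of many transcripts, not their level, differed between the pools was an idea drawn from this disagreement, so the share does not test it and it stays open. Whether falls belong to single probes or to transcripts also stays open for the genes called lower, whose other probes had a median of -0.3 (interval -0.417 to -0.176), between the bounds set beforehand. RNA integrity, labelling yield along a transcript and a true change of transcript ends coincide with the pools here and were not tested.

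The fibroblast and extracellular matrix list had a median of -0.445 (95% interval -0.637 to -0.277). The endothelial median was 0.0248 (interval -0.196 to 0.15), inside its random range, so the endothelial list did not fall as a whole. With a limma adjusted p under 0.05 and no fold limit, 2 endothelial genes were higher and 6 lower. The fibroblast list was put forward for its low median, so a higher endothelial median was largely fixed in advance. Less of every stromal cell type is therefore not excluded by that contrast. The upper end of the fibroblast list's interval, -0.277, lies below the lowest median of 10000 matched random lists (-0.25). In these pools the list thus fell further than genes of like signal. The list was put forward by its place among these same random lists, and the interval treats its genes as independent. A general excess of falls among genes of like signal is therefore not tested anew as a cause of the fall. Probes differing within a transcript stay open for it: 18 other tested probes of the list's genes had a median of -0.255 (interval -0.447 to -0.0534), which meets neither bound set beforehand. A smaller share of fibroblasts in the knockout papillomas and a lower matrix expression per cell may both lie behind it, and 1 pool per genotype cannot separate either from differences between individual tumours.

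The 1126 probes past the threshold compare with 0 for the highest of the other splits of the 6 arrays into 3 and 3 (limma; up to 488 probes at an unadjusted p under 0.05 with no fold limit, against 10552); the real split was the 1 split of 10 with as many, and 10 splits cannot give a share under 0.05. Each other split puts arrays of both pools on each side, so the difference between the pools counts there as spread. A count near 0 was therefore fixed in advance, and the contrast with 1126 tests neither chance nor the genotype. Mixed strain background could place FVB or C57bl6 variants around the targeted locus in probe sites. Among the 200 tested genes nearest to Atf2, 100 on each side, 11 passed the threshold, against 423 of 11884 others (odds ratio 1.58, 95% interval 0.768 to 2.92, two-sided Fisher's exact p = 0.174). This interval holds both no excess and a 2-fold excess, so an effect of variants near the locus stays open, and strain variants elsewhere were not tested.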
